A study of Homo sapiens with 6 samples.

How the data were processed

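The material was 6 samples of MRC5 cells in the state of cancer-associated fibroblasts, as the labels call them, each measured on 1 Affymetrix array. MRC5 is a human lung fibroblast cell line. Total RNA was turned into biotinylated cDNA, per the labels' protocols. The labels put 3 arrays in the group transfected with a control siRNA (si-Ctrl) and 3 in the group transfected with an siRNA against Dicer1 (si-Dicer1), all at 72 h. Group and replicate number were taken from the sample titles. The labels do not say whether the replicates were separate cultures, so that p-values measure only the spread between these arrays. The number of arrays limits the precision.

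The values analysed were the authors' deposited log2 expression values, 1 per row and array, between 1.89 and 14.2. They were made with RMA, per the submitters' processing notes. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of each row, which pulls the arrays towards 1 distribution and narrows small differences between them. The software version, the probe annotation behind the summary and the genome build are not given in the sources used here. The array medians still differed slightly, so that quantile normalization and median centring of the deposited values were both run as alternatives.

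The table held 70460 rows, of which 65535 had a value on every array and 4925 had none on any array. The platform annotation gave 1 gene symbol for 23771 of the rows with values, several for 1543 and none for 40221. Symbols were updated through their Entrez numbers or, failing that, current symbols and synonyms of the NCBI RefSeq gene table, which paired 23768 of the 23771 rows with a current gene. In 409 sets of rows, 1443 rows in all, the 6 values equalled those of another row to 6 decimals.

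The comparison of si-Dicer1 with si-Ctrl was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, all 6 arrays, no covariate). Rows with exactly 1 symbol were tested, with the row of the highest mean over all 6 arrays standing for a gene with several, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. On simulated data with the means and spread of the 22434 rows tested, in which 50 rows were changed at each fold, limma called 52% of the 1.25-fold changes, 84% of the 1.5-fold, 96% of the 2-fold and 100% of the 3-fold changes, with 12 false calls. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, where at least 5 members were measured, and with fry, which asks whether the members move one way.

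The 25 lists covered microRNA machinery, microRNA host transcripts, targets of let-7, miR-21, miR-29 and the miR-17 family, the interferon response, antigen presentation, contractile myofibroblast genes, cancer-associated fibroblast markers, extracellular matrix, matrix proteases and their inhibitors, growth factors, inflammatory cytokines, G2/M and S phase genes, replication-dependent histones, p53 targets, the TGF-beta and YAP response, hypoxia and glycolysis, the unfolded protein and integrated stress response, cholesterol synthesis, and epithelial, endothelial and leukocyte markers. The rule for named genes took DICER1 and all measured members of the microRNA machinery, the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each list past the threshold, or the 2 with the largest changes as values where fewer than 2 passed. Tests, lists, this rule and the alternatives were fixed before the data were examined, except those named as chosen afterwards. A test of microRNA seed sites was planned and not run, since untranslated region sequences were not used here.

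Whether each value belongs to the name of its row was checked after the data were seen, with 2 measures. The first compared the levels of rows named for housekeeping families (ribosomal and mitochondrial ribosomal proteins, proteasome, respiratory chain, spliceosome, translation initiation and chaperonin subunits) with those named for tissue-restricted families (olfactory, taste and vomeronasal receptors, keratin-associated proteins, beta-defensins and late cornified envelope proteins), as the chance that a row of the first kind is higher than a row of the second. The second compared members of the fibroblast marker and matrix lists with members of the epithelial, endothelial and leukocyte lists in the same way.

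For the closing section, runs of values were searched for their place along the order of row IDs. Each stretch of at least 100 consecutive unnamed rows with values was taken as a run, its mean levels over all 6 arrays were freed of a running mean over 51 rows, and they were correlated with the presence of a gene symbol at every place along the order. A place was accepted when its r, multiplied by the square root of the number of rows, exceeded that of the second-best place by at least 3. Local offsets of up to 10 rows on either side were then found with a forward-backward pass (20 level classes, a chance of 0.001 of a new offset from row to row), and a value counted as placed at a posterior of at least 0.99. The search used no difference between the groups. Chance places were sought with values shuffled within each stretch, with phases randomized so that the values and the likeness of neighbours were kept (amplitude-adjusted Fourier transform), and with each stretch reversed. On a simulated table whose names were sorted apart from its values, with levels drawn from the placed values themselves, 12 of 23 stretches were accepted and 11044 of 11091 placed values stood at their true row (99.58%). Since these levels were drawn row by row and take the places as right, this share is not an error rate for the real places. On simulated data for the 5299 placed genes, limma called 84% of the 1.25-fold changes, 98% of the 1.5-fold and 100% of the 2-fold and 3-fold changes, with 16 false calls. The placed genes were then tested like the others, adjusted over the placed genes. These steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots were drawn with matplotlib 3.10.9.

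Alternatives were quantile normalization, centring each array on its median, only features above the median level, the mean of a gene's rows, a trended and robust variance, the replicate number as a block, each array left out in turn, a threshold of 0.01, all rows with or without a symbol, and camera with an estimated correlation.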

Results

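To determine how the transcriptome of lung fibroblasts in the cancer-associated state differed after transfection with an siRNA against Dicer1, RNA of 6 MRC5 samples was measured on arrays, 3 labelled si-Ctrl and 3 labelled si-Dicer1, each 72 h after transfection. DICER1 is the enzyme that cuts microRNA precursors into mature microRNAs. Every array gave 65535 values. The array medians lay between 5.10 and 5.21 on the log2 scale. The highest median was that of si-Ctrl replicate 2, whose mean correlation with the other si-Ctrl arrays across rows was 0.997 and with the si-Dicer1 arrays 0.995. The first principal component held 44.2% of the variance and parted the groups, with scores from -33.65 to -4.97 for the si-Ctrl arrays and from 15.36 to 17.36 for the si-Dicer1 arrays. Replicate 2 of si-Ctrl stood farthest out on it. No array was a copy of another, since the values of any pair differed with an SD of at least 0.13.

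The row that the platform annotation names DICER1 (TC14001472.hg.1) did not differ between the groups. Its log2 values were 6.97, 7.11 and 7.09 on the si-Ctrl arrays and 7.05, 7.09 and 7.14 on the si-Dicer1 arrays. The means were 7.05 ± 0.08 and 7.09 ± 0.05 (SD, n = 3 each), a log2 change of 0.04 (SE 0.05) with a limma Benjamini-Hochberg adjusted p of 0.691. Without si-Ctrl replicate 1 the change was -0.003. Under its deposited name the targeted gene thus gave no sign of the siRNA, and the groups are called below by their labels.

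**Figure D1:**
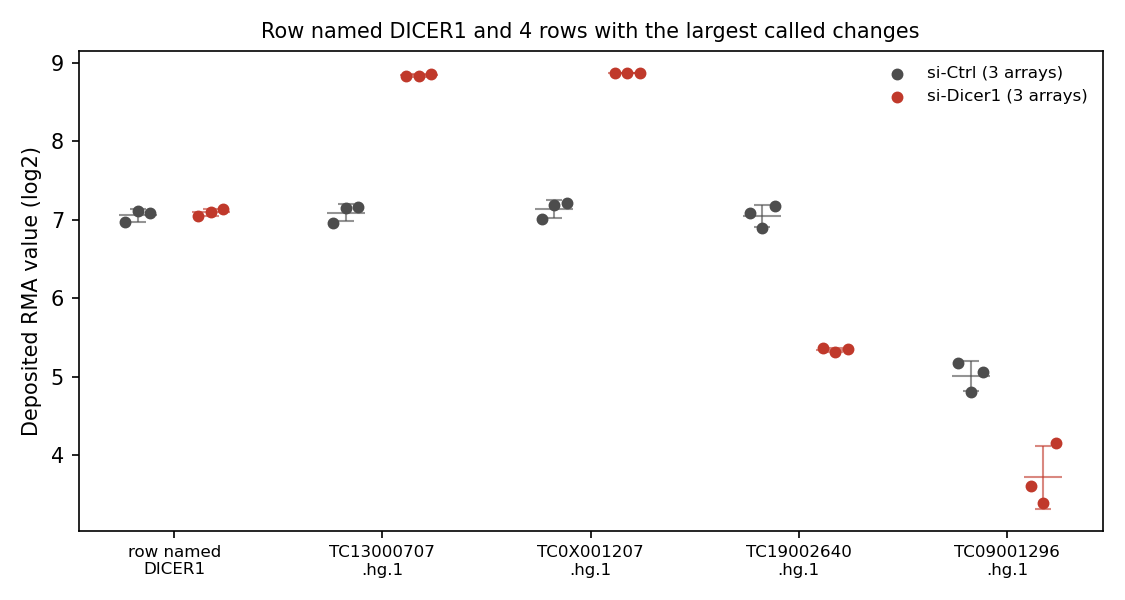
Deposited log2 values (vertical axis) of the row named DICER1 and of the 2 rows that rose most and the 2 that fell most among called rows with 1 symbol, in si-Ctrl (grey) and si-Dicer1 (red), with the 3 arrays of a group as points, their mean as a horizontal mark and the SD as a bar. The row named DICER1 stayed near 7 in both groups, while TC13000707.hg.1 went from 7.09 to 8.84. The row IDs are labels as deposited and may not belong to these values.

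Several other rows had levels unlike those of the named genes in fibroblasts, so the pairing of names and values was examined for the whole table. The row named VIM, the intermediate filament protein of mesenchymal cells, had a mean of 3.15, and the row named S100A6, a calcium-binding protein abundant in fibroblasts, had a mean of 2.51. Both lay below the lower quartile of every array, which was between 3.66 and 3.73. The row named ACTB, cytoplasmic actin, had a mean of 4.70, below the median of every array, and the row named EEF1A1, a translation elongation factor, had a mean of 5.11, close to the array medians. The row named ALB, serum albumin of the liver, had a mean of 8.98, above the upper quartile of every array. Other rows did not stand out as low: COL1A1, the main chain of collagen I, had a mean of 9.50, GAPDH, a glycolytic enzyme, 8.65, FBN1, fibrillin 1, 8.14 and MMP2, gelatinase A, 7.11. All were above the upper quartile of every array, which alone does not show that the names fit. These genes were chosen after their values were seen.

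The 277 rows named for housekeeping families had a median of 4.40, and the 629 rows named for genes of tissue-restricted families, such as olfactory receptors, had a median of 3.95. The housekeeping names were matched by pattern and took in some pseudogenes, such as CCT6P1 and EIF3FP3. A gene could have several rows. The chance that a row with a housekeeping name was higher than a row with a tissue-restricted name was 0.587. Names from the lists of fibroblast markers and extracellular matrix had a median of 4.60 over 63 rows, and names from the epithelial, endothelial and leukocyte lists had a median of 5.86 over 53 rows. The chance that the fibroblast name was the higher one was 0.382. These checks were added after the data were seen. Because level and name went together poorly, changes between the groups are given below by row, and no gene is called changed from its deposited row. The names were reached through the row IDs, so an ID may belong to other values just as a name may. The IDs serve below only as labels of the deposited rows.

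**Figure D2:**
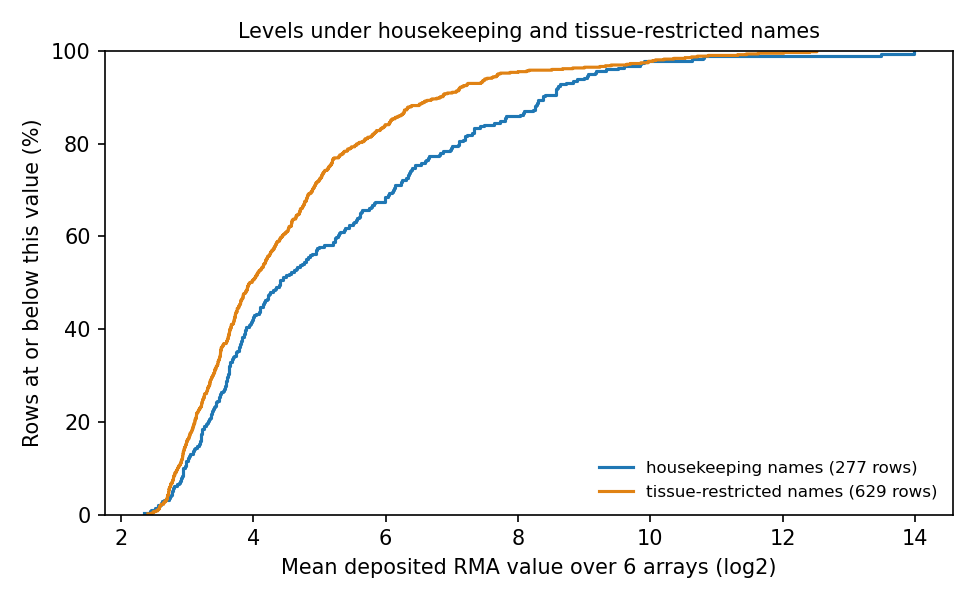
Cumulative share of rows (vertical axis, percent) against the mean deposited log2 value over the 6 arrays (horizontal axis), for the 277 rows with housekeeping names (blue) and the 629 rows with tissue-restricted names (orange). The medians are 4.40 and 3.95, and both curves start at the same low values, with the housekeeping curve to the right between about 4 and 9.

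Between the arrays labelled si-Dicer1 and those labelled si-Ctrl, 439 rows were higher and 362 lower among the 22434 rows that stand for 1 symbol each (limma, Benjamini-Hochberg adjusted p under 0.05). Most of these changes were small. Of the 801 rows, 94.4% changed by less than 1.5-fold, and 3 higher and 3 lower rows reached 2-fold. The largest rise was that of TC13000707.hg.1, from 7.09 ± 0.11 to 8.84 ± 0.02 (SD, n = 3 each), a log2 change of 1.75 (SE 0.06) with a limma adjusted p of 0.000302. TC0X001207.hg.1 rose from 7.13 to 8.87, with values close to those of TC13000707.hg.1 on each array. The largest fall was that of TC19002640.hg.1, from 7.05 ± 0.14 to 5.34 ± 0.02 (SD, n = 3 each), a log2 change of -1.70 (SE 0.07) with a limma adjusted p of 0.00055. TC09001296.hg.1 fell from 5.01 ± 0.19 to 3.72 ± 0.40 (SD, n = 3 each), with a limma adjusted p of 0.0236.

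The groups did not overlap in 30.3% of these rows, where chance gives 10% for 3 arrays against 3 if no shift is common to the rows. The si-Ctrl medians (5.12 to 5.21) all lay above the si-Dicer1 medians (5.10 to 5.11), and such a shift can raise this share. The share was not computed after centring. Over all 65535 rows, with or without a symbol, 992 were higher and 983 lower, 14 and 7 of them at least 2-fold. After each array was centred on its median, the split moved from 439 higher and 362 lower (54.8% higher) to 352 higher and 125 lower (73.8% higher). The counts also depended on which array was left out. Without si-Ctrl replicate 1 they were 79 and 68, without si-Ctrl replicate 3 they were 225 and 146, and without replicates 1, 2 and 3 of si-Dicer1 they were 61 and 46, 53 and 43, and 60 and 47. Without si-Ctrl replicate 2, the array that stood apart, 332 rows were higher and 297 lower.

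Of the 25 gene lists, from microRNA machinery and microRNA targets to matrix genes, cytokines and cell type markers, none passed camera's threshold under the deposited names. The lowest camera adjusted p was 0.927, 0 lists had an unadjusted camera p under 0.05, while fry, which does not compare a list with other genes, gave 2 lists past an adjusted p of 0.05 (antigen presentation and G2/M genes) and 9 at an unadjusted one. Since the names went with the levels poorly, this result describes the names in the table and not the pathways.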

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

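The use of placed rows, and the alternatives on equal values, the genes tested, the places, and the variance and adjustment over all rows, were chosen after seeing the data, while the other alternatives were planned. For the rows under deposited names (439 higher and 362 lower), the counts were 964 and 733 with rows above the median level only, 968 and 646 with a trended and robust variance, 992 and 983 over all rows, 70 and 58 at a threshold of 0.01, 352 and 125 after median centring, and 107 and 96 with the deposited names of the placed genes only. Leaving out each array in turn gave 53 to 332 higher and 43 to 297 lower. The replicate block, which lowers the residual degrees of freedom, left 40 higher and 23 lower. The replicate numbers did not pair the arrays: deviations of same-numbered arrays from their group means correlated with r of 0.013, 0.018 and -0.014 across rows, and 3 of the 6 arrays correlated best with their own number. Quantile normalization, the mean of a gene's rows and 1 row for each set of equal values kept the counts within 1.5-fold. The row named DICER1 changed by -0.003 to 0.066 when an array was left out, past the threshold under none of 14 alternatives, and by -0.71 when the names were moved to the placed rows. With the names moved, 2 of 17 lists were called, against 0 of 17 under the deposited names of the placed genes.

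For the placed genes (488 higher and 509 lower), the counts were 526 and 221 after median centring, 260 and 255 with the replicate block, 163 and 157 at a threshold of 0.01, 288 and 250 with the variance fitted over all rows of the table, and 147 and 142 when p was adjusted over all rows as well. Leaving out each array in turn gave 163 to 587 higher and 182 to 644 lower. DICER1 at its placed row stayed past the threshold under 16 alternatives, between -0.75 and -0.66. A margin of at least 5 leaves out the stretch that holds DICER1, so that this alternative gave no value for it. The number of lists called, 2, was 4 with quantile normalization and with median centring, 0 with genes above the median level only, 0 with an estimated correlation, and 1 to 3 when an array was left out. For the cases above where no reason is given, the cause was not tested. Besides DICER1, 64 of 75 named genes passed the threshold. Single genes were followed under 12 alternatives, without the threshold of 0.01, the variance and adjustment over all rows, the margin and the Entrez numbers, and 8 of the 64 had no value above the median level. Wherever they had a value under these 12, 47 kept the call, and 17 lost it under at least 1: CCL11, CSF3, IFIT2, CEBPB, DHCR7, ANGPT1, AURKA, MYL9, DDX17, IGF2BP1, COL1A1, P4HA1, KLF10, TNKS2, CCNE2, DORIP1 and PLAG1. None of the 64 changed direction. KRT8 passed under 3 alternatives and IDI1 under 1 (above the median level, adjusted p 0.0494). Of the named genes that did not pass, NLRC5 changed from -0.03 to 0.006 with quantile normalization and 0.019 with median centring, and MIR100HG lay between -0.019 and 0.043 when an array was left out. The seed site alternatives were not run.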

Other observations

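The gene-level values in this part rest on a hypothesis, namely that the names in the table were sorted apart from the values and that runs of values can be put back at their rows. The tests of that hypothesis, of its explanations and of microRNA targets taken as 1 list, and the use of placed rows, were chosen after the result was seen, while the fits, lists and rule for named genes applied to those rows were the planned ones. With the names moved, 5299 genes had a placed value, and DICER1 was among the genes that fell. At the placed row its log2 values were 8.61, 8.51 and 8.66 on the si-Ctrl arrays and 7.90, 7.88 and 7.87 on the si-Dicer1 arrays, a log2 change of -0.71 (SE 0.04), or 1.64-fold, with a limma adjusted p of 0.000285. DDX17, an RNA helicase of the microRNA-processing complex and the other measured member of the microRNA machinery, rose by 0.13 (SE 0.03). Its call was lost under 5 alternatives. Of the 5299 genes, 488 were higher and 509 lower, 0 and 3 of them at least 2-fold. After median centring, the split moved from 48.9% to 70.4% higher, with 526 higher and 221 lower. The counts were 246 and 250 without si-Ctrl replicate 1, 526 and 551 without si-Ctrl replicate 2, 587 and 644 without si-Ctrl replicate 3, and 180 and 182, 163 and 182, and 192 and 198 without si-Dicer1 replicates 1, 2 and 3. With the variance fitted over all 65535 rows, 288 genes were higher and 250 lower, and with p adjusted over all rows as well, 147 and 142.

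Of the called genes at the placed rows, CEMIP, which degrades hyaluronan, fell most, 2.86-fold from 11.60 to 10.09, and CCL2, a chemokine that attracts monocytes, fell 2.71-fold from 11.00 to 9.56. KRTAP1-5, a keratin-associated protein, fell 2.41-fold from 9.65 to 8.38. Its family is among the tissue-restricted ones, whose names had a median of only 3.64 at the placed rows. Whether its place is wrong was not tested. SULF1, an extracellular heparan sulfatase, fell by 0.89 on the log2 scale, the potassium channel gene KCNJ2 fell by 0.79, EXPH5 fell by 0.70, the nuclear factor TOX fell by 0.69 and CCN4, a matricellular protein, fell by 0.68. CNTNAP1 fell by 0.67, and SERPINF1, the anti-angiogenic factor PEDF, and C1R, a complement protease, each fell by 0.63. Of the genes that rose, COLEC10, a collectin, rose most, 1.88-fold, followed by SEMA7A, a membrane-anchored semaphorin, with a log2 change of 0.81 and CARD16, a caspase-recruitment protein, with 0.80. LPCAT2 rose by 0.79, E2F7, a repressor of E2F targets, by 0.78, MMP16, a membrane-type metalloprotease, by 0.77 and STC1, a secreted glycoprotein, by 0.72. SLC6A15, TNFRSF10D, MMP3 (stromelysin-1), MIR635 and AMIGO2 rose by 0.65, 0.65, 0.60, 0.59 and 0.57. Each of these genes had a limma adjusted p of 0.00611 or lower, and the arrays of both groups did not overlap, as the rule for naming them asks.

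Of the 17 lists with at least 5 placed members, 2 passed the threshold with camera at the preset correlation. Among 15 matrix proteases and inhibitors, 7 rose, 1 fell and 7 did not pass (limma camera adjusted p 0.0111, limma fry adjusted p 0.000585). This call was lost with an estimated correlation (camera adjusted p = 0.345) and with genes above the median level only (0.104). MMP16, MMP3 and MMP2 (gelatinase A, 10.90 to 11.30, SE 0.03) rose, and PLAT, the tissue plasminogen activator, fell by 0.47 (SE 0.03). Among the rises, MMP12 (3.55 to 3.93) and MMP10 (4.54 to 4.79) lay below the median of every array. Among 10 interferon response genes, 6 fell and 4 did not pass (limma camera adjusted p 0.0111, limma fry adjusted p 0.000585). This call was lost with an estimated correlation (camera adjusted p = 0.345), with genes above the median level only (0.104) and without si-Ctrl replicate 3 (0.0777). IFIT1 fell by 0.45 (SE 0.06), from 4.27 to 3.82, below the median of every array. IFIT2 fell by 0.33 (SE 0.06), IFI35 fell by 0.32 (SE 0.03) and IFITM1 fell by 0.21 (SE 0.03). The call of IFIT2 was lost under 5 alternatives, among them quantile normalization (limma adjusted p 0.0596) and median centring (0.0516). The other lists did not pass camera's threshold. Extracellular matrix passed it with median centring (limma camera adjusted p 0.048), the mean of a gene's rows (0.0245) and a trended and robust variance (0.0421), and growth factors passed it with quantile normalization (0.0472), median centring (0.048) and without si-Ctrl replicate 2 (0.0432). Quantile normalization called 4 lists, namely matrix proteases, the interferon response, growth factors and another list whose values are not given here. Of all lists tested, fry gave an adjusted p under 0.05 for 9.

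Of 9 extracellular matrix genes, 4 rose and 1 fell: LUM (lumican) rose by 0.43, FBN1 (fibrillin 1) by 0.26, P4HA1, a collagen prolyl hydroxylase, by 0.18 and COL1A1, the main chain of collagen I, by 0.14. Of 5 cancer-associated fibroblast markers, LUM rose, THY1, a surface glycoprotein of fibroblasts, fell by 0.37 and 3 did not pass. Of 5 contractile genes, ITGA11 rose by 0.40, MYL9 by 0.14, the cofactor MYOCD fell by 0.33 and 2 did not pass. Of 11 growth factors, 5 fell, among them LIF, which fell by 0.50, PDGFD, which fell by 0.36, and ANGPT1, which fell by 0.26, while KITLG rose by 0.19. Of 7 inflammatory cytokines, CCL2 (log2 change -1.44), CCL11 (-0.19) and CSF3 (-0.19) fell and 4 did not pass. The calls of CCL11 and CSF3 were lost under 9 and 8 alternatives, among them quantile normalization (limma adjusted p 0.0602 and 0.0615) and median centring (0.0716 and 0.0655). Those of COL1A1, P4HA1, MYL9 and ANGPT1 were each lost under 5. Of 10 hypoxia and glycolysis genes, 5 fell and 2 rose, led by ADM, which fell by 0.48, ALDOC, which fell by 0.39, and NDRG1, which fell by 0.25. Each of these changes had an SE of at most 0.051.

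Of 6 G2/M genes, AURKA fell by 0.18 and 5 did not pass, with UBE2C at -0.11. Of 11 S phase genes, CCNE2 rose by 0.23 and 10 did not pass, with PRIM1 at 0.17. Of 9 p53 targets, RRM2B and KITLG rose by 0.28 and 0.19, TP53INP1, TNFRSF10B and DDB2 fell and 4 did not pass. The 8 genes of the unfolded protein and integrated stress response held 2 that rose (HERPUD1, 0.25, and SEL1L, 0.22) and 1 that fell (CEBPB, -0.16), with a median of -0.04 where camera's direction was up against the other genes. Of 4 TGF-beta and YAP response genes, KLF10 rose by 0.13 and LTBP3 fell by 0.24. Of 3 cholesterol synthesis genes, DHCR7 fell by 0.16, with IDI1 at 0.09. The calls of CCNE2 and KLF10 were each lost under 5 alternatives, that of CEBPB under 6, that of AURKA under 2 and that of DHCR7 under 1. The 5 epithelial markers (KRT8 -0.10, CDH1 -0.08), 6 endothelial markers (CLDN5 -0.17, CDH5 -0.07) and 3 leukocyte markers (CD163 -0.12, ITGAM -0.09) held no call, although KRT8 passed with quantile normalization (limma adjusted p 0.0432), with genes above the median level only (0.0164) and with a trended and robust variance (0.0247). There were 0 replication-dependent histones placed, and 1 gene each for antigen presentation (NLRC5, -0.03) and microRNA hosts (MIR100HG, 0.02). Adjusted over the list alone, the counts differed for 7 lower interferon genes, 5 higher matrix genes, 7 lower growth factors, 4 higher p53 targets, 7 lower hypoxia genes and 2 higher cholesterol genes, and matched those over all placed genes for the other lists.

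A fall of DICER1 could release microRNA targets. This hypothesis was tested on the target lists of let-7, miR-21, miR-29 and the miR-17 family taken as 1 list, of whose 123 members 25 were placed. Of these, 7 rose and 2 fell. The let-7 targets held CCND2 (0.28), DORIP1 (0.27) and IGF2BP1 (0.16) as rises and RDH10 (-0.32) as a fall among 13. The single miR-21 target, PLAG1, rose by 0.34, the 5 miR-29 targets held FBN1 and COL1A1 as rises, and the 6 miR-17 family targets held TNKS2 (0.18) as a rise and TP53INP1 (-0.27) as a fall. The calls of DORIP1, IGF2BP1 and PLAG1 were each lost under 3 alternatives, and those of COL1A1 and TNKS2 under 5. CCND2, FBN1, RDH10 and TP53INP1 kept theirs under the 12 alternatives, wherever they had a value. The medians of the let-7, miR-29 and miR-17 family lists were below 0 (-0.027, -0.023 and -0.019), although camera's direction was up against the other genes for each. Limma's camera gave p = 0.0751 for the pooled list, upwards against the other genes, and p = 0.38 with an estimated correlation, while limma's fry, which does not compare the list with other genes, gave p = 0.0427, with a median change of -0.02 in the list and -0.05 in all placed genes. A release of targets may therefore be present or not, and the reason why the tests differ was not tested.

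Concerning the names themselves, the row named DICER1 did not fall, and names went with levels poorly. RNA of another cell type is argued against by the level of the housekeeping families, since a housekeeping name was higher than a tissue-restricted name with a chance of only 0.587. These families also hold some members that not every cell uses, such as PSMB8 and PSMB9 of the antigen presentation list, and the name patterns took in pseudogenes. Such rows can lower that chance even where names are right. The chance of 0.587 was known before this argument was made, and it is part of the pattern to be explained. Swapped arrays, with the names right, are argued against as the explanation of that pattern. No split of the 6 arrays into 3 and 3 parted the row named DICER1 by more than 0.08 on the log2 scale. A swap also leaves the means of rows as they are. If the names are wrong, that row cannot show whether arrays were swapped. A sorting of the names apart from the values fits a test that could have gone the other way: the search for places used only means over all arrays, and the value placed at DICER1 changed by -0.714, a fall reached by 42 of 65535 rows (0.0641%). The number of rows with values, 65535, is also the most that an older spreadsheet format holds below its heading line, so the table may have been cut and sorted in a spreadsheet, which was not tested. None of the 25314 named rows was in a searched stretch. Their neighbouring values correlated with r of 0.028 in ID order and 0.2 in order of symbol. In 1000 random orders r lay between -0.02 and 0.023, and for unnamed rows in ID order it was 0.24. A sorting by symbol would give such a pattern, but it does not show where single values belong. Rows of the same symbol or gene family also stand together in order of symbol, and random orders break them up. The comparison with random orders therefore cannot tell whether the names are right. Whether the sorting covers each of the rows that were not placed stays open.

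The places themselves could have arisen by accident, which was tested by shuffling the values within each of the 23 stretches 100 times. The shuffled stretches gave a clear place 0 times, with a largest margin of 1.55, against 13 of the real stretches with margins from 3.18 to 9.20, and all 13 accepted places followed the order of the stretches in the table. Since shuffling removes the likeness of neighbouring values, the stretches were also randomized 100 times with it kept (median r of neighbours 0.202, against 0.201 in the real stretches), which gave a clear place 0 times and a largest margin of 1.58. Of the 23 stretches in reversed order 0 had a clear place. At those places r lay between 0.245 and 0.415, against 0.105 to 0.178 at the second-best place. With the names moved, a housekeeping gene was higher than a tissue-restricted gene with a chance of 0.946 (61 and 150 rows), against 0.677 for the same names as deposited, and a gene of the fibroblast lists was higher than one of the other cell type lists with a chance of 0.738 (14 and 15 rows), against 0.267. At the placed rows GAPDH had a mean of 12.75, TUBA1B 13.08 and COL1A1 12.66. All 9712 values placed both by gene symbols and by Entrez numbers stood at the same row. The second indicator was the first without the rows that lack an Entrez number. The match was thus largely fixed in advance and says little about the places. The stretch that holds DICER1 had a margin of 4.76 and the row a posterior of 0.99998, but a place can still be wrong by some rows, as in the simulated table, where 11044 of 11091 were right.

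The 6 arrays can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. The real split called 801 rows under deposited names and 997 placed genes, and the highest of the other splits called 0 in both cases, so that 1 of the 10 splits gave as many. For the placed gene lists, 3 of the 10 splits gave at least the 2 lists of the real split, and the highest of the others gave 3. All 3 of those splits set si-Ctrl replicates 1 and 3 on one side, and those besides the real one set replicate 2 of si-Ctrl, the array that stood apart, with si-Dicer1 arrays.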
